A study of Rattus norvegicus with 2 samples.

How the data were processed

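Skin of male Sprague-Dawley rats was measured in 1 library per group, irradiated with 45 Gy or from a non-irradiated area. Per the labels' protocols, total RNA was isolated with TRIzol, ribosomal RNA was removed with a Ribo-Zero kit, and stranded total RNA libraries were made with a TruSeq kit and sequenced on an Illumina HiSeq. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks and Cuffdiff, without their roles or settings. The genome build and annotation release are not given in the sources used here. How reads shared by near-identical copies were counted, and whether counting used the strand, is not stated either, so values of gene families and overlapping genes are uncertain.

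The deposited table gives 22714 rows, all of protein-coding genes with Ensembl identifiers, symbols and coordinates, and for each library an FPKM value and a count value. Per the file headers, the FPKM values were made by the authors and relate reads to transcript length and library size; they sum to 1017840 in the irradiated and 1002190 in the non-irradiated library. The deposited count columns hold a scaled signal and not raw counts. Their low values are multiples of 1 step per library, 1.05 in the irradiated and 0.951 in the non-irradiated library. Of the values above 0, 97.7% and 98.0% were whole multiples within 0.01 of a read plus 1e-05 of a read for each read of the value, a tolerance that stays far below a read except for the highest genes. Dividing by the step gave estimated totals of 11197467 and 12649557 reads on protein-coding genes. The scaled sums were 11806699 and 12028861. In the irradiated library 7005 rows were at 0, and in the non-irradiated library 8647. No count model was run, since the values are not raw counts and there is 1 library per group. The table held no column of the authors' own comparison, and 0 per-sample columns were left unused.

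Libraries were grouped by the source label, and table columns were matched to libraries by title. The title NC of the irradiated library is not expanded in the labels. Rows that share a symbol were summed, which gave 22312 genes; 49 rows without a symbol kept their identifier. Genes with a mean of at least 1 FPKM over both libraries were kept, 9743 in all or 43.7%. The ratio was log2((irradiated FPKM + 1)/(non-irradiated FPKM + 1)), and the rule for a difference was 2-fold. No p-value was computed. Counting intervals are 95% exact Clopper-Pearson intervals for the ratio of scaled counts in 2 libraries, from the estimated reads; shares of reads have intervals of the same kind. Intervals cover counting error only, and may understate it, since PCR copies are not independent molecules. They are on the scale of scaled counts with no pseudocount, so the log2 ratio of a gene with low FPKM can lie outside its interval. FPKM and scaled counts also differ for some genes with higher FPKM, abundant or not. Pgk1 had a log2 ratio of 0.07 in FPKM and an interval of -0.10 to -0.05 in scaled counts. The intervals therefore do not bound the FPKM ratio. Where a library had no reads for a gene, the ratio was taken against a floor of 3 reads in that library. Such a ratio leaves out the counting error of the library that had reads, and it has no confidence level.

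Before the data were examined, 43 gene lists were fixed from the tissue and treatment, with 920 members. Of these 889 matched a gene of the table, 882 by symbol, 2 by symbol in another case, 4 by a synonym in the table and 1 through RefSeq names of assembly GRCr8, and 31 did not match. For the 36 lists with at least 5 measured members, the median log2 ratio was placed among 10000 random lists drawn in 20 bins of mean expression; a list stands apart outside their central 95%. By this rule 11 lists stood apart as higher and 8 as lower. The lists overlap, so they are not independent of each other. Named genes were chosen by a rule fixed at the same time: the 12 largest positive and 12 largest negative ratios among genes with a regular symbol, leaving out predicted genes and antigen receptor segments. For each list described, up to 4 members were taken, 2 with the largest absolute ratio and 2 with the highest mean. Some members that this rule names are not reported here.

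The steps were tested on simulated data drawn from Poisson counts at the real means and library sizes, for the irradiated against non-irradiated comparison on 9708 genes. Changed genes were drawn only from those with a mean of at least 2 FPKM, so recovery below that level was not tested. Of 50 genes each, the 2-fold rule found 50 that were 4-fold higher and 49 that were 4-fold lower. The rule also found 47 that were 3-fold higher and 46 that were 3-fold lower. It called 23 of 9508 unchanged genes. Of 500 random lists of 20 unchanged genes 4.20% stood apart, and all of 200 lists with 12 raised members did. With 12 of 20 members raised 3-fold or 4-fold, that last result follows largely from the construction. These simulations hold no variation between animals.

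Other settings fixed at the same time were a pseudocount of 0.1, no filter and a mean of at least 5 FPKM, rescaling to a median ratio of 0, by a trimmed mean (30% of ratios and 5% of levels), to a fixed total, and to a fixed total without the 100 highest genes. Thresholds of 1.5-fold and 4-fold, the highest row per gene, and leaving out the muscle, follicle and adipocyte lists with rescaling to a fixed total were fixed as well. For lists, no matching, 10 bins and leaving out shared members were also fixed. Chosen after seeing the data were scaled counts at a fixed total plus 1, a minimum of 20 reads, and leaving out the epithelial and liver lists. Further lists of general epithelial genes and of liver genes, and pathways as the table's pathway column names them, were also taken up after the values had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Bootstrap intervals over list members used 10000 draws.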

Results

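The series compared the mRNA of rat skin after ionising radiation with that of skin from an area that was not irradiated, in a model of radiation-induced skin fibrosis. Male Sprague-Dawley rats of 4 weeks had received a single dose of 45 Gy from an electron beam. There was 1 library of irradiated skin and 1 library of non-irradiated skin, so no difference below has a replicate check and no test of the condition was possible. The statements describe these 2 libraries. The labels do not say when the skin was taken, how many animals gave it or whether their RNA was pooled. The group of each library was taken from its source label; the title of the irradiated library reads NC, which the labels do not expand. In other studies NC often stands for a negative control, which would conflict with the source label of 45 Gy. The direction of every comparison rests on the source labels and would be inverted if these were exchanged. The deposited table held 22714 protein-coding rows, which gave 22312 genes after rows with the same symbol were summed. An estimated 11197467 reads lay on these genes in the irradiated library and 12649557 in the non-irradiated library.

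Both libraries held muscle transcripts as well as those of skin. The skeletal muscle list took 35.5% of the reads of the irradiated library (95% exact Clopper-Pearson interval 35.4 to 35.5%) and 38.7% of those of the non-irradiated library (38.7 to 38.8%). Mylpf, a light chain of fast muscle myosin, stood at 92922 FPKM (read density relative to transcript length and library size) in the irradiated and 81247 FPKM in the non-irradiated library. Tnnc2, troponin C of fast muscle, stood at 74216 and 84551 FPKM. The 10 genes with the most reads took 30.4% of the irradiated and 33.9% of the non-irradiated library.

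Genes of the epidermis, the hair follicle and the sebaceous gland were higher in the irradiated library, together with genes of cell division. The median of the interferon response list was higher as well, at 0.76 on the log2 scale, while 15 of its 22 measured members lay within 2-fold. The list medians of extracellular matrix, fibroblast and endothelial genes were slightly lower, at -0.27, -0.29 and -0.35 on the log2 scale, while most members of each list lay within 2-fold. Krt14, a keratin of basal keratinocytes, stood at 618 FPKM in the irradiated against 11.99 FPKM in the non-irradiated library, while Col3a1, a chain of fibrillar collagen, stood at 284 against 414 FPKM. Of 9743 genes with a mean of at least 1 FPKM, 945 were at least 2-fold higher and 149 at least 2-fold lower in the irradiated library, and 8649 lay within 2-fold. Of the higher genes 94 had no reads in the non-irradiated library, and of the lower genes 11 had none in the irradiated library. With 3 reads put in place of those zeros, 918 genes were higher and 144 lower. The median log2 ratio over all measured genes was 0.21. Ratios are log2((irradiated FPKM + 1)/(non-irradiated FPKM + 1)), which understates the difference of genes with low values. When the libraries were rescaled so that the median ratio was 0, 693 genes were higher and 261 lower, so that the share of higher genes among those called was 72.6% in place of 86.4%.

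**Figure D1:**
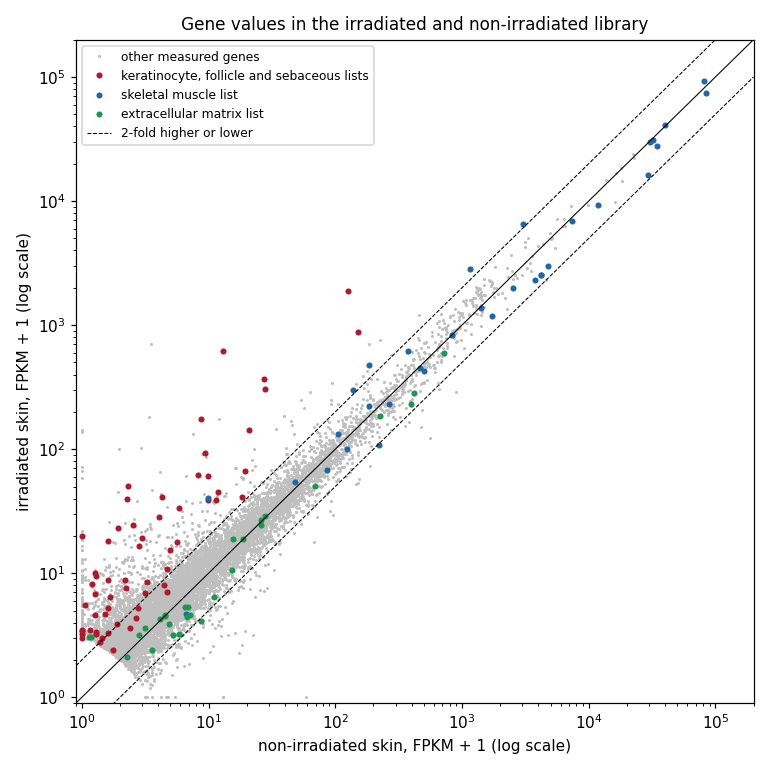
Each point is a gene with a mean of at least 1 FPKM; the horizontal axis is FPKM + 1 in the non-irradiated library and the vertical axis FPKM + 1 in the irradiated library, both on log scales, with a solid line of equal values and dashed lines at 2-fold. Of the 60 measured genes of the keratinocyte, follicle and sebaceous lists (red), 54 lie on or above the upper dashed line, while the skeletal muscle (blue) and extracellular matrix (green) genes lie mostly between the dashed lines.

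Each gene list was set against 10000 random lists of the same size matched on expression, and the percentile of its median is a description of these libraries. The extracellular matrix list had a median log2 ratio of -0.27 (percentile 0), or -0.48 relative to the median of all genes. Of its 29 measured members, 2 were at least 2-fold higher, 1 was at least 2-fold lower and 26 lay within 2-fold. The higher members were Tnc (log2 1.43), which encodes tenascin C, and Thbs1 (1.37), which encodes thrombospondin 1; they rested on 151 against 11 reads and 52 against 5 reads. Col3a1 had a log2 ratio of -0.54, and the log2 ratio of its scaled counts had a 95% counting interval of -0.57 to -0.52. Sparc, a protein that binds collagen, had a log2 ratio of -0.26. The medians of the fibroblast list (-0.29, percentile 0.05) and the endothelial list (-0.35, percentile 0.01) were lower in the irradiated library as well. Of 17 fibroblast markers, 1 was at least 2-fold higher, 1 was at least 2-fold lower and 15 lay within 2-fold. S100a4 stood at 570 against 276 FPKM, and Pi16 at 6.20 against 26.2 FPKM. Of 13 endothelial markers none was at least 2-fold higher and 2 were at least 2-fold lower, namely Emcn (log2 -1.14) and Plvap (-1.13).

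Genes that process or crosslink collagen had a median of -0.00 (percentile 5.11). PCOLCE2, an enhancer of procollagen processing, was the single one of 16 members beyond 2-fold, at 1.57 against 9.94 FPKM (log2 -2.09). Serpinh1, the collagen chaperone, had a log2 ratio of -0.73. The TGF-beta list had a median of 0.17 (percentile 25.4), with 1 of 19 members at least 2-fold higher and 18 within 2-fold. That member was Tgif1, a repressor of TGF-beta signalling, at 6.05 against 0.830 FPKM. The metalloproteinases and their inhibitors had a median of 0.20 (percentile 36.7), with Timp4 (log2 -1.25) the single one of 11 beyond 2-fold and Timp1 at 17.0 against 15.6 FPKM. The medians of the TGF-beta and metalloproteinase lists lay close to that of all genes and turned to -0.07 and -0.00 under the trimmed-mean scaling. In the same libraries the medians of the fibroblast and endothelial lists were -0.29 and -0.35.

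Of the 14 measured genes of the myofibroblast and smooth muscle list, 5 were at least 2-fold higher, 1 was lower and 8 lay within 2-fold. Acta2, the alpha smooth muscle actin gene on this list, matched no gene of the table and was not assessed. The list's median was 0.44, at percentile 97.1. The contractile genes Cnn1 (6.04 against 0.282 FPKM) and Actg2 (6.10 against 0.317 FPKM) had log2 ratios of 2.46 and 2.43 but only 5 reads each in the non-irradiated library. Tpm1 and Tpm2, which skeletal muscle also expresses, had log2 ratios of 0.04 and -0.32. The list passed the upper bound of the percentiles with 10 bins of expression, on scaled counts and without the 100 highest genes, where its median was 0.92.

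Genes of cell division were higher in the irradiated library. Of the 26 measured members of the proliferation list, 15 were at least 2-fold higher and 11 lay within 2-fold, and the median was 1.07 (percentile 100). Aurka, a mitotic kinase, stood at 9.05 against 1.16 FPKM (log2 2.22), and the helicase subunit Mcm6 at 4.14 against 0.739 FPKM. Pcna, the sliding clamp of DNA replication, stood at 31.7 against 14.7 FPKM. Genes of the DNA damage response and repair had a median of 0.61 (percentile 99.4), although none of their 17 measured members reached 2-fold; with no filter on low values the percentile was 96.4. Msh6 had the largest of these ratios, at 0.98. Of 20 measured p53 targets, 3 were at least 2-fold higher and 17 lay within 2-fold, with a median of 0.34 (percentile 90.9). Perp, a p53 target that also encodes a desmosomal protein of stratified epithelium, had a log2 ratio of 3.17. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 57.9 against 17.7 FPKM, and Ccng1 was nearly equal at 357 and 356 FPKM. The senescence list had a median of 0.44 (percentile 89.6), with 2 of 14 members, Cxcl1 and Cdkn1a, at least 2-fold higher. The basal keratinocyte list was higher in the same library, with a median of 2.42.

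The interferon response list had a median of 0.76 (percentile 99.98). Of its 22 measured members, 7 were at least 2-fold higher and 15 lay within 2-fold. Irf7, a transcription factor of the type I interferon response, stood at 19.2 against 3.04 FPKM, and Isg15, a ubiquitin-like protein induced by interferon, at 18.6 against 3.69 FPKM. The basal, differentiating and stress-type keratinocyte lists were higher in the same library, with medians of 2.42, 2.83 and 2.39. The list of inflammatory cytokines and chemokines had a median of 0.19 (percentile 36.0), with 4 of 14 measured members at least 2-fold higher and none at least 2-fold lower. Cxcl1, a chemokine that attracts neutrophils, had a log2 ratio of 2.33 and Cxcl10, a chemokine induced by interferon, 1.55, on 60 against 5 and 34 against 4 reads. Cxcl12 stood at 16.5 against 26.4 FPKM (log2 -0.64). The log2 ratio of its scaled counts had a nearer interval of -0.47 to -0.01, so the size of this difference is uncertain. With a mean of at least 5 FPKM, or without the 100 highest genes, the cytokine list's median turned to -0.33 and -0.15, at percentiles 1.13 and 1.72. The macrophage list lay near the median of all genes (median 0.05, percentile 8.99), and antigen presentation had a median of -0.01 (percentile 11.8). Complement genes had a median of -0.13 (percentile 1.97), with Cfi (log2 1.56) at least 2-fold higher and Serping1 (-1.01) at least 2-fold lower; with a mean of at least 5 FPKM the percentile was 7.08.

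The lists of keratinocytes and the sebaceous gland had the highest medians of all lists, and hair follicle genes were higher as well. Of 11 basal keratinocyte genes, 10 were at least 2-fold higher, and the median was 2.42 (percentile 100). Krt14 (ENSRNOG00000003899, chromosome 10, 87910657 to 87914716, minus strand) had a log2 ratio of 5.58, with a counting interval of 5.48 to 5.88 for the ratio of its scaled counts, and its partner Krt5 stood at 369 against 26.4 FPKM. All 10 measured genes of differentiating keratinocytes were at least 2-fold higher (median 2.83), among them Lgals7, a galectin of stratified epithelium, at 1883 against 125 FPKM. Of 11 stress-type keratinocyte genes 10 were at least 2-fold higher (median 2.39), with Krt17 at 306 against 26.8 FPKM and Fabp5 at 878 against 151 FPKM. Of 17 hair follicle genes 14 were at least 2-fold higher (median 1.33), with Krt25 at 65.6 against 18.3 FPKM. Of 11 sebaceous gland genes 10 were at least 2-fold higher (median 2.61), with Elovl3 at 49.8 against 1.32 FPKM and Elovl4 at 38.5 against 1.28 FPKM, both of which elongate fatty acids. None of the members of these 5 lists was at least 2-fold lower.

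Of the other cell types, the neutrophil list had a median of 1.95 (percentile 99.99) over 5 measured genes, of which S100a8, S100a9 and Lcn2 also stand on the stress-type keratinocyte list. With no filter on low values its percentile was 60.9. The Schwann and nerve list had a median of 1.13 (percentile 99.9), with 4 of 7 members at least 2-fold higher, such as the myelin gene Mbp (log2 2.79). The blood list had a median of -0.35 (percentile 0.72), with Hba1 at 222 against 392 FPKM. The adipocyte list had a median of -0.08 (percentile 2.72), with 1 of 13 members at least 2-fold higher, 1 at least 2-fold lower and 11 within 2-fold. Fabp4, the fatty acid binding protein of fat cells, stood at 166 against 383 FPKM and Cebpa, a transcription factor of fat cells, at 2.72 against 0.833 FPKM. The adipocyte list passed the lower bound with a mean of at least 5 FPKM (median -0.55, percentile 0.565) and under the trimmed-mean scaling (median -0.48, percentile 0.17), among other settings. Pericyte genes had a median of 0.58 (percentile 84.1). Both measured mast cell genes were lower in the irradiated library: Cma1, a mast cell chymase, stood at 2.21 against 21.4 FPKM and Cpa3, a mast cell carboxypeptidase, at 0.512 against 4.19 FPKM. The lists of lymphatic endothelium, T and NK cells, B and plasma cells, mast cells, dendritic cells, melanocytes and eccrine epithelium had fewer than 5 measured members and no percentile.

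Skeletal muscle genes had a median of -0.10 (percentile 1.47). Of 33 members, 5 were at least 2-fold higher, 1 was at least 2-fold lower and 27 lay within 2-fold. Myh3, the embryonic myosin heavy chain, stood at 39.2 against 8.98 FPKM (log2 2.01) and Myh2, the heavy chain of fast oxidative fibres, at 480 against 185 FPKM (log2 1.37). Without the 100 highest genes the list's percentile was 64.5, and with no filter it was 3.54 and on scaled counts 3.67.

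Among the remaining lists, Wnt pathway genes had a median of -0.14 (percentile 0.425), with 4 of 13 members at least 2-fold higher and 2 at least 2-fold lower. Wnt3 had a log2 ratio of 2.38, while Sfrp2 and Sfrp4, secreted proteins that bind Wnt, had -2.14 and -1.30; without the 100 highest genes the median turned to 0.95. Fatty acid genes had a median of 0.14 (percentile 51.8), with 3 of 19 members at least 2-fold higher. Among them were Fasn, the fatty acid synthase, at log2 2.47 and Acly, which makes cytosolic acetyl-CoA, at log2 2.21. The fatty acid list stood at percentile 99.14 with no filter (median 0.45) and 99.87 without the 100 highest genes (median 0.56), while its median turned to -0.11 under the trimmed-mean scaling. The sebaceous gland list was higher in the same library, with a median of 2.61. The hypoxia list had a median of -0.01 (percentile 5.10), with the glucose transporter gene Slc2a1 at log2 2.14 and Ndrg1 at 1.13. The oxidative stress list had a median of 0.05 (percentile 32.4), with Mt1, a metallothionein, at 167 against 44.0 FPKM and Gclc, of glutathione synthesis, at 5.57 against 1.36 FPKM. Nuclear genes of mitochondrial respiration had a median of 0.07 (percentile 68.8), and all 25 lay within 2-fold.

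The lists taken up to describe RNA quality gave mixed results, and they are not a measure of RNA integrity. The immediate early and heat shock list had a median of -0.23 (percentile 0.11), with Fos at 9.63 against 32.0 FPKM; without the 100 highest genes the percentile was 3.19. Hspa8 on the same list went the other way at 89.7 against 7.83 FPKM. This heat shock cognate gene has near-identical copies that can share its reads, which makes its value uncertain. Ribosomal protein genes had a median of 0.45 (percentile 100), or 0.24 relative to all genes, with 39 of 40 members within 2-fold. The mitochondrially encoded genes had a median of 0.04 (percentile 57.2), and the reference genes 0.20 (percentile 81.8), with Gapdh at -0.04.

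**Figure D2:**
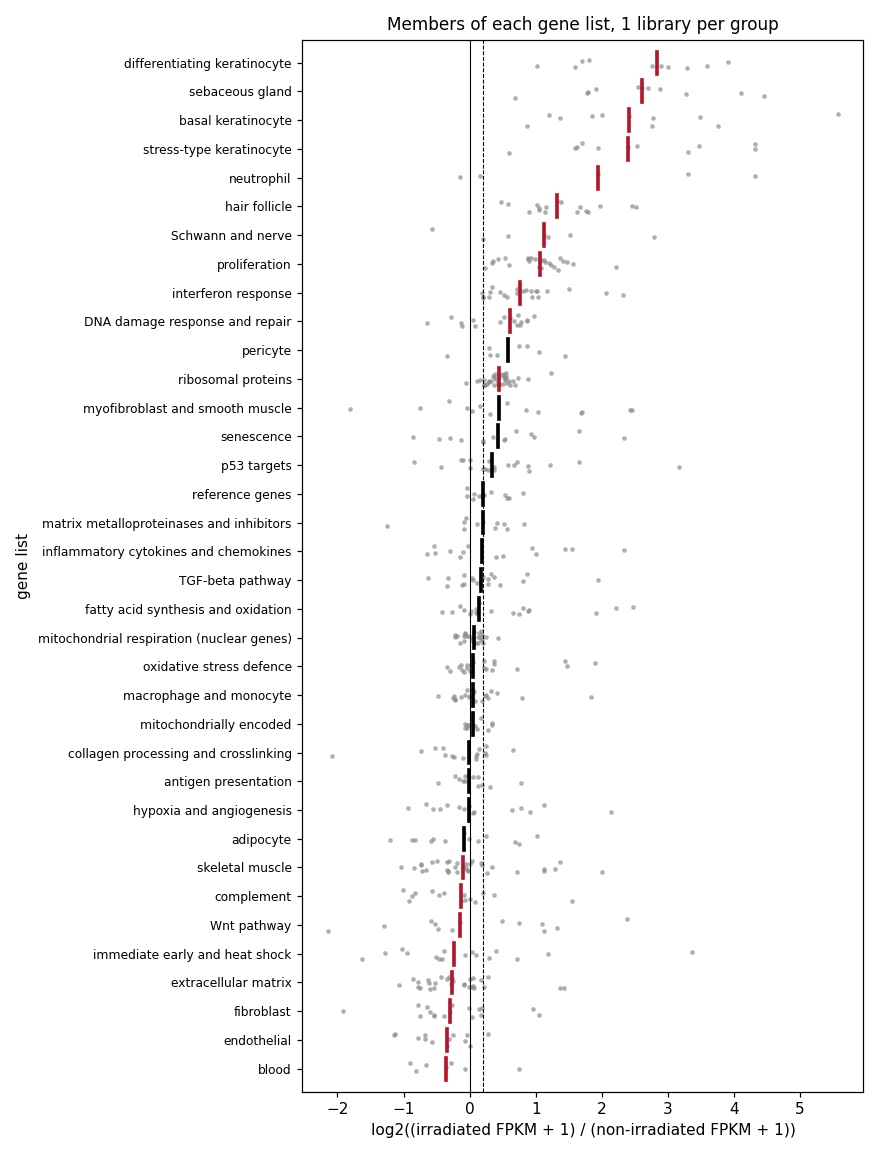
Each grey point is 1 measured gene of a list, placed on the horizontal axis by its log2 ratio of irradiated over non-irradiated FPKM, each plus 1; vertical spread within a line is for legibility. Thick bars are list medians, red where the median lies outside the central 95% of the matched random lists, and the dashed line marks the median of all measured genes at 0.21; keratinocyte and sebaceous lists lie at 2.39 to 2.83 and the blood list lowest at -0.35.

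The named genes with the largest positive ratios included stefins, which inhibit cysteine proteases, and S100 proteins, which bind calcium. Stfa3 (ENSRNOG00000033933, chromosome 11, 70398921 to 70403785, plus strand) stood at 703 against 2.51 FPKM on 1957 against 8 reads, with a counting interval of 7.10 to 9.30 for the log2 ratio. Its relatives Stfa2l3 and Stfa2l1 had no reads in the non-irradiated library, and their scaled counts were at least 30.7-fold and at least 19.2-fold higher against a floor of 3 reads. S100a8 stood at 173 against 7.78 FPKM. The stefin genes are near-identical copies and their separate values are uncertain. S100a14 was at least 9.61-fold higher on 26 reads, and Wfdc18, a protein with a whey acidic protein domain, at least 78.4-fold higher on 212 reads. Krt79, a keratin of the sebaceous duct, had a log2 ratio of 4.57, Elovl3 had 4.45 and Rpl12-ps1, whose name marks a pseudogene, 5.11. Alb and Apoc1, genes of liver-secreted plasma proteins, had no reads in the non-irradiated library. They were at least 173-fold and at least 71.7-fold higher against the floor of 3 reads. The lower ends of the counting intervals lay below such floor ratios, at 140-fold for Alb and 57.8-fold for Apoc1.

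The named genes with the largest negative ratios included the mast cell proteases Mcpt1l1 (log2 -2.81) and Cma1 (-2.80), which lie close together on chromosome 15 and belong to 1 family, so that reads shared between them leave their values uncertain. Gsn, which encodes the actin-severing protein gelsolin (ENSRNOG00000018991, chromosome 3, 19799928 to 19826452, plus strand), stood at 121 against 555 FPKM on 3635 against 18483 reads, with a counting interval of -2.25 to -2.15 for the log2 ratio. Mstn, the muscle growth inhibitor myostatin, stood at 6.58 against 27.7 FPKM and Myoc, myocilin, at 16.8 against 67.1 FPKM. Sfrp2 and PCOLCE2 had log2 ratios of -2.14 and -2.09, Ccs, the copper chaperone of superoxide dismutase, -2.17, and Aph1b, a subunit of gamma-secretase, -2.00. Lyrm4 (3 against 23 reads) and Adig (1 against 9 reads) rested on few reads, with counting intervals of -5.17 to -1.06 and -8.47 to -0.17. Mzt1 had 3 reads in the non-irradiated library and none in the irradiated one, too few for a ratio. The build of these coordinates is not given in the sources used here.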

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

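No paired analysis was possible because each group had 1 library. The use of scaled counts, of a minimum of 20 reads and of leaving out the epithelial and liver lists was chosen after seeing the data. The 945 higher and 149 lower genes became 1562 and 252 with a pseudocount of 0.1, 321 and 84 with a mean of at least 5 FPKM, 1956 and 443 without the 100 highest genes, 2315 and 509 at 1.5-fold and 229 and 19 at 4-fold. The lower genes became 261 with the median ratio at 0, 274 with the trimmed mean and 247 without the muscle, follicle and adipocyte lists, while the higher genes stayed within 1.5 times of 945 there. Stricter thresholds and filters leave fewer genes by construction, and a looser threshold leaves more. Rescaling to a fixed total without the 100 highest genes raises every other value against the fixed pseudocount and the floor. The same holds without the muscle, follicle and adipocyte lists. A smaller pseudocount enlarges ratios, and the median and trimmed-mean scalings move all ratios downward, also by construction. All settings not named here kept both counts within 1.5 times.

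Of 36 lists, 23 kept their side of the percentile bounds in every setting in which they were run. The collagen processing list passed the lower bound on scaled counts (percentile 0.48). The myofibroblast list passed the upper bound without the 100 highest genes (99.99), on scaled counts (98.49) and with 10 bins (97.53). The p53 targets did so without the 100 highest genes (97.845). The cytokine list passed the lower bound with a mean of at least 5 FPKM (1.13) and without the 100 highest genes (1.72). The Wnt list turned to percentile 98.72 with no filter and 99.56 without the 100 highest genes, and the skeletal muscle list to 64.5 without them. The lists of DNA damage, complement, neutrophils and immediate early genes lost, and those of hypoxia, fatty acids and adipocytes gained, a place outside the bounds in at least 1 setting. For adipocytes these were no filter (percentile 0.27), a mean of at least 5 FPKM (0.565), the median ratio at 0 (0.21), the trimmed mean (0.17) and at least 20 reads (0.24). The cause was not tested. The sign of the median kept under all scalings for 25 lists and flipped for 11, all with a median within 0.21 of 0. Genes with few reads, such as Mzt1 and Adig, are limited by depth.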

Other observations

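The tests of depth, scaling, the stress-type response and the stromal share, and all pathway values, were chosen only after the results were seen; those of the epithelial share and of liver genes were written before their lists were looked at. Genes of cholesterol synthesis, which no fixed list covered, were higher in the irradiated library. The table's pathway column held 268 pathways with at least 10 measured genes. Of these, 23 lay above and 24 below the central 95% of matched random lists. For lists of randomly drawn genes, 6.7 would fall on each side on average. The pathways share genes and are not independent of each other, so the excess over 6.7 was not tested. Steroid biosynthesis had a median log2 ratio of 1.57 (percentile 100), with 10 of 14 genes at least 2-fold higher. Sqle, the squalene epoxidase, stood at 12.01 against 1.19 FPKM. In the same library the sebaceous gland list was higher with a median of 2.61, as were the keratinocyte lists with medians of 2.39 to 2.83. The p53 signaling pathway had a median of 0.38 (percentile 98.4), with 11 of 47 genes at least 2-fold higher and none at least 2-fold lower, whereas the fixed list of p53 targets lay within the bounds. ECM-receptor interaction had a median of 0.18 (percentile 23.3), with 11 of 37 genes at least 2-fold higher and none at least 2-fold lower, unlike the fixed matrix list. Focal adhesion lay within the bounds, with a median of 0.20 (percentile 56.6). Of its 122 genes 15 were at least 2-fold higher and none at least 2-fold lower, against 945 and 149 of all 9743 measured genes. Retinol metabolism had a median of 0.76 (percentile 99.96) and the spliceosome 0.38 (percentile 100). The renin-angiotensin pathway had a median of -0.35 (percentile 0.02), with 4 of 12 genes at least 2-fold lower, among them the mast cell genes Cma1 and Cpa3 and the angiotensin receptor gene Agtr1a at 0.881 against 3.06 FPKM.

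Muscle genes differed within their class, in genes chosen after their values were seen. Ankrd1, a stress-responsive gene of striated muscle, stood at 174 against 11.2 FPKM. Myh1, a fast myosin heavy chain, stood at 2822 against 1157 FPKM and Mb, myoglobin, at 6566 against 3014 FPKM. Myh4, the heavy chain of the fastest glycolytic fibres, stood at 3014 against 4747 FPKM and Ckm, muscle creatine kinase, at 16291 against 29251 FPKM. Myh7, of slow fibres, had a log2 ratio of -0.35. Some widely expressed genes also stood far apart, such as Hnrnpa3 at 17.0 against 0.756 FPKM and Yme1l1 at 0.263 against 2.60 FPKM. They rested on 201 against 10 reads and 7 against 77 reads. How reads shared by near-identical copies were counted is not stated, so both values are uncertain.

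Keratinocyte and gland genes were higher in the irradiated library, with 54 of 60 members of the 5 lists at least 2-fold higher. That share restates the pattern, so the epithelial share was tested on genes outside those lists in its place. Library depth or scaling is argued against, since 1 factor per library moves all genes alike and these lists lay 2.03 log2 units above the skeletal muscle list (bootstrap interval over members 1.78 to 2.72). More epithelium in the irradiated piece may account for the pattern. Of 31 measured genes of a further list of general epithelial genes, 24 or 77.4% were at least 2-fold higher, against 945 of all 9743 measured genes. The list had 53 genes in the table, and all 31 measured ones also had at least 3 reads in the non-irradiated library. The filter on the mean favours genes that are high in the irradiated library. Cdh1 (log2 2.26) and Pkp3 (2.34), at 0.565 and 0.914 FPKM in the non-irradiated library, passed only through it. How far the filter raised the share was not tested. A specific stress-type response of keratinocytes cannot be told apart from more epithelium, as the stress-type list's median minus the basal list's was -0.025 with an interval of -1.16 to 1.46. Whether a larger epithelial share came from where the piece was taken or from irradiation stays open with 1 library per group.

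Several liver genes were read in the irradiated library with at most 1 read in the other: Alb had 467 against 0 reads, Apoc1 194 against 0, Serpina1 169 against 1 and Ttr 78 against 0. Secreted acute-phase genes expressed in the tissue alone are argued against, since 12 of 17 liver enzyme genes (70.6%) also had at least 3 reads there and more than in the other library, such as Cyp2e1 (40 against 0) and Hpd (46 against 0). RNA or reads from liver may therefore be the source, at a small share: all the liver genes looked at had 3383 reads, or 0.0302% of the irradiated library, against 722 in the other, where Tf held most of them (528 against 567 reads). All 16 secreted genes of the list had higher FPKM there as well, but 6 of them and 2 of the enzymes also had at least 3 reads in the non-irradiated library, and 3 enzymes, among them Cyp2c11, had none in the irradiated one. Tissue carried over and reads assigned from another library were not separated.

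The medians of the matrix, fibroblast and endothelial lists were lower in the irradiated library, although most members lay within 2-fold and the table's ECM-receptor pathway (median 0.18) was not lower. Scaling of the libraries is argued against as the whole cause, since the matrix list lay -0.48 log2 units from the median of all genes (bootstrap interval -0.73 to -0.21), a distance that 1 factor per library leaves in place. The 3 lists' median lay -0.19 from that of the skeletal muscle list, with an interval of -0.42 to 0.14. This interval covers both signs, so a smaller stromal share relative to muscle was not shown. The test cannot separate such a share from an effect of irradiation. Lower medians were also seen outside the stroma lists: skeletal muscle and blood lay -0.31 and -0.56 from the median of all genes. Muscle lay closer to its matched random lists, at -0.10 against 0.03, and at percentile 64.5 without the 100 highest genes. Blood lay at -0.35 against 0.09, and the matrix list at -0.27 against 0.21. Pericyte and Schwann lists lay above the median of all genes, by 0.37 and 0.92, but the pericyte list stayed within the bounds (percentile 84.1). A response of the stroma to irradiation stays open and untested, since the groups have 1 library each.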
